A study of Mus musculus with 16 samples.

How the data were processed

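RNA had been measured in 16 bulk libraries of sorted mouse germinal centre B cells, 4 per group, with 3' end sequencing in which transcripts receive a barcode and a unique molecular identifier at reverse transcription, are pooled and are amplified linearly. Per the labels, the groups were LZ and DZ cells taken 4 h after anti-CD40 or isotype antibody. The number of mice, the antibody dose and the sorting gates are not in the labels.

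The deposited table holds raw counts of UMI for 9443 genes in each library. In it the authors also give a normalized signal, which is the raw count divided by 1 size factor per library, and for 4 comparisons a log2 fold change from DESeq2. The deposited p-values were computed by the authors with DESeq2. The authors' adjusted p-values are a Benjamini-Hochberg adjustment over all listed genes. Per the labels, reads were trimmed with cutadapt, aligned with STAR to mm10 and counted with HTSeq, without versions. Every listed gene reaches at least 6 counts in some library, and no immunoglobulin or mitochondrially encoded gene is listed. Of the symbols, 9289 were found in GENCODE vM21, which gave positions and GC content, and 9407 in RefSeq. The raw counts were used for every test, and the deposited fold changes only for counts of shared genes.

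Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (minimum count 10), which left 6824 genes holding 98.6% of all UMI. Libraries were scaled with TMM factors, and a model with 4 group means was fitted to all 16 libraries with robust quasi-likelihood dispersions. The 5 comparisons were anti-CD40 against isotype in the LZ and in the DZ, the difference of those changes between zones (an interaction), and LZ against DZ under isotype and under anti-CD40. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes of its comparison. CPM were TMM-scaled except for the summed markers of other cell types, which used the library total. Principal components used log2 CPM with a prior count of 2, and the first and next component held 32.1% and 28.0% of the variance.

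A total of 27 gene lists were written before the data were examined: LZ markers, DZ markers, NF-kB targets, Myc targets, mTORC1 with amino acid and one-carbon metabolism, glycolysis, oxidative phosphorylation, G1/S, G2/M, MHC class II presentation, T cell costimulation and adhesion, B cell receptor and immediate early genes, B cell receptor signalling components, germinal centre identity, plasma cell differentiation, memory and naive B cells with egress, migration and positioning, apoptosis regulators, somatic hypermutation and DNA repair, FoxO1 and PI3K, interferon response, heat shock and dissociation stress, mitochondrially encoded genes, and markers of T cells, of myeloid and dendritic cells, of stromal and follicular dendritic cells, and of red cells and platelets. Lists with at least 5 tested members, 22 of them, were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01 between genes. Members of a list were also adjusted over the list alone. The lists overlap: LZ markers and NF-kB targets share 8 tested genes, apoptosis regulators and NF-kB targets 7, and DZ markers and germinal centre identity 5.

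The text names up to 8 of the largest rises and 8 of the largest falls per comparison among genes that passed, with every library of a group above every library of the other and a mean of at least 20 CPM in the higher group, and for the interaction up to 5 each way without the separation. Immunoglobulin and T cell receptor segments, ribosomal and mitochondrial genes and unnamed predicted genes were left out of that choice. Myc and Cd40 were always named, and up to 4 members of a list with the smallest adjusted p. The comparisons, lists, naming rule and the alternatives below, except those named as added, were all fixed before the data were examined. Myc, Cd40 and library measures were also compared with exact permutation tests over the 70 arrangements of 4 against 4 libraries, in Python 3.11.15 with SciPy 1.17.1 and NumPy 2.4.6; figures were drawn with Matplotlib 3.10.9.

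Depth was 493131 to 1473415 UMI per library, so that 1 UMI stood for 0.679 to 2.03 CPM. Replicates varied beyond counting error, with a chi-square per degree of freedom of 1.73 to 11.7. Tested on 20 simulated sets, edgeR recovered on average 39.4% of 2-fold changes in the LZ (range 32.0 to 48.0%) and 45.8% in the DZ (34.7 to 59.4%). For 4-fold changes it recovered 90.0% and 93.7%. The share of false calls averaged 4.15% in the LZ (1.69 to 6.02%) and 4.64% in the DZ (1.34 to 8.61%). The number of sets was raised to 20 after single sets had been seen to differ.

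Other choices tried were DESeq2 1.42.0, limma-voom, RLE and upper quartile factors, no low-count filter (9443 genes), a stricter filter of 20 counts in 4 libraries (5885 genes), a fit of only the groups compared, immunoglobulin genes left out, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and fry. Added after the data were seen were the libraries numbered 4 left out, a GC correction that removed from each library a trend of log2 CPM on the GC content of the last 500 transcript bases, and both that correction and the block together. GC content was known for 6738 tested genes (98.7%). The authors' regularised log values were not used, since the tests need counts.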

Results

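The series measured polyadenylated RNA of germinal centre B cells from mouse lymph nodes, 4 h after anti-CD40 or an isotype control antibody was given in vivo. CD40 is the receptor through which helper T cells signal to B cells, and an anti-CD40 antibody stands in for that signal. Cells were sorted as light zone (LZ), where B cells receive T cell help, or dark zone (DZ), where they divide and mutate their antibody genes. The 16 libraries formed 4 groups of 4: isotype LZ, anti-CD40 LZ, isotype DZ and anti-CD40 DZ. The series title concerns Myc and the choice of B cells by T cells, so Myc and Cd40 were followed in every comparison.

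Totals ran from 493131 to 1473415 unique molecular identifiers (UMI) per library, and between 8718 and 9353 genes were detected. Isotype LZ libraries held 616625 ± 78942 UMI (SD, n = 4) and isotype DZ libraries 1050004 ± 299465 (exact permutation test, two-sided p = 0.0286, adjusted p = 0.229 over 16 tests of library measures). A single UMI in the shallowest library corresponded to 2.03 CPM (UMI scaled to a common library size). A count of 0 there allowed up to 6.08 CPM, for counting error only. In 6824 genes deep enough to test, the biological coefficient of variation was 24.6%. The labels do not say whether replicates came from separate mice. Every p below from a test between libraries therefore measures only the spread between these samples. The 4 libraries numbered 4, 1 in each group, differed from the other 12 in 2451 genes with group in the model, and counts without them are given beside each result.

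Anti-CD40 raised Myc in the LZ from 32.5 ± 13 to 269 ± 57.7 CPM (mean ± SD, n = 4; log2 fold change 3.05, SE 0.30, adjusted p = 2.23e-06). Myc, a transcription factor that drives cell growth, lies on chromosome 15 at 61985391 to 61990374 of GRCm38 (ENSMUSG00000022346.15). Cd40 itself, on chromosome 2 at 165055627 to 165072948 (ENSMUSG00000017652.16), rose from 248 ± 14.1 to 812 ± 59.6 CPM (1.71, SE 0.13, adjusted p = 2.71e-07). Genes that Myc is known to induce for ribosome production and growth rose together: 48 of 51 tested members rose and none fell, with 49 adjusted over the list alone. Among them were Srm, the spermidine synthase, from 113 ± 20.4 to 523 ± 140.5 CPM (log2 fold change 2.20, SE 0.22, adjusted p = 2.59e-06). The small nucleolar protein gene Nhp2 rose as well (1.84, SE 0.18, adjusted p = 1.61e-06). The nucleostemin gene Gnl3 rose by 1.95 on the log2 scale (SE 0.23, adjusted p = 1.11e-05).

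Targets of NF-kB, the factor that CD40 activates, also rose in the LZ: 23 of 36 rose and none fell, with 25 adjusted over the list alone. Nfkbia, which encodes the NF-kB inhibitor IkBa, went from 752 ± 79.5 to 3396 ± 407 CPM (n = 4; log2 fold change 2.17, SE 0.17, adjusted p = 2.71e-07). Ebi3, a cytokine subunit gene, rose by 3.23 (log2, SE 0.27, adjusted p = 5.04e-07), and Birc3, an inhibitor of apoptosis, by 2.25 (SE 0.22, adjusted p = 1.61e-06). Of 21 LZ marker genes, 15 rose and 2 fell (17 and 3 adjusted over the list alone), and 8 of the 21 also belong to the NF-kB list. Irf4, a transcription factor gene among the LZ markers, rose from 46.2 ± 9.82 to 396 ± 73.8 CPM (3.09, SE 0.25, adjusted p = 3.01e-07). Of 22 apoptosis regulators, 9 rose and 3 fell (9 and 7 adjusted over the list alone); Bcl2l1, which encodes the survival protein Bcl-xL, rose by 3.21 (SE 0.37, adjusted p = 1.19e-05). The apoptosis list as a whole did not pass (camera adjusted p = 0.0723).

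Genes of the DZ and of germinal centre identity fell in the LZ after anti-CD40. Of 18 DZ markers, 7 fell and 1 rose (8 and 1 adjusted over the list alone). Among those that fell were Mybl1 (log2 fold change -1.95, SE 0.33, adjusted p = 3.69e-04) and Mxd3, whose protein competes with Myc for its partner Max (-1.84, SE 0.31, adjusted p = 3.67e-04). Of 23 germinal centre identity genes, 9 fell and 1 rose, as when adjusted over the list alone; the list's camera call (adjusted p = 3.16e-04) was lost at adjusted p = 0.0697 with an estimated correlation. S1pr2, a receptor that keeps B cells inside the germinal centre, went from 449.8 ± 40.2 to 123 ± 38.1 CPM (n = 4; log2 fold change -1.87, SE 0.19, adjusted p = 3.14e-06). Efnb1, the ephrin B1 gene, went from 197 ± 25.9 to 40.6 ± 5.69 CPM (-2.27, SE 0.19, adjusted p = 5.07e-07). In the FoxO1 and PI3K list 7 of 16 genes fell and none rose (10 adjusted over the list alone). Klf2 was at -2.75 (log2, SE 0.40, adjusted p = 9.60e-05) and Foxo1 at -0.76 (SE 0.18, adjusted p = 0.00606). Of 30 B cell receptor signalling components 8 fell and none rose, also 8 adjusted over the list alone. The inhibitory receptor genes Cd22 (-1.19, SE 0.15, adjusted p = 2.99e-05) and Siglecg (-1.14, SE 0.18, adjusted p = 2.45e-04) were among them. Of 34 G2/M genes, which act in mitosis, 8 fell and none rose (14 adjusted over the list alone), including the kinesin gene Cenpe (-1.34, SE 0.27, adjusted p = 0.00211).

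In the mTORC1, amino acid and one-carbon list 13 of 26 genes rose and 1 fell (16 and 1 adjusted over the list alone). Its camera call (adjusted p = 3.25e-06) was lost at adjusted p = 0.0904 with an estimated correlation. The serine hydroxymethyltransferase gene Shmt2 rose by 1.54 (log2, SE 0.17, adjusted p = 7.54e-06), and Ddit4, an inhibitor of mTORC1, fell (-1.73, SE 0.30, adjusted p = 5.27e-04). Among heat shock and dissociation stress genes 4 of 9 rose and none fell (7 and 1 adjusted over the list alone), a camera call (adjusted p = 0.00867) lost at adjusted p = 0.113 with an estimated correlation. Hspd1, also in the Myc target list, rose by 1.45 (SE 0.23, adjusted p = 2.18e-04). Glycolysis (2 of 12 rose, also 2 adjusted over the list alone, camera adjusted p = 0.171) did not pass, although Ldha rose by 0.76 (SE 0.15, adjusted p = 0.00122). Oxidative phosphorylation (4 of 28 rose, 3 adjusted over the list alone, camera adjusted p = 0.228) did not pass either, and its median of 0.10 turned negative under upper quartile scaling.

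Several LZ lists held members that went both ways. T cell costimulation and adhesion had 8 of 18 genes up and 1 down (9 and 2 adjusted over the list alone): Tnfsf9, the 4-1BB ligand gene, rose by 3.18 (SE 0.33, adjusted p = 3.05e-06). Its camera call (adjusted p = 0.0142) was lost at adjusted p = 0.113 with an estimated correlation. Memory, naive and egress genes had 2 of 12 up and 7 down (2 and 8 adjusted over the list alone). Fcer2a, which encodes CD23, rose (1.59, SE 0.14, adjusted p = 9.15e-07), while S1pr4, a sphingosine phosphate receptor gene, fell (-1.84, SE 0.29, adjusted p = 2.29e-04). That list's camera call (adjusted p = 0.0180) was lost with an estimated correlation (adjusted p = 0.116) and without isotype LZ library 1, 2 or 3 (adjusted p = 0.177, 0.208 and 0.196). Migration and positioning had 3 of 16 up and 4 down (3 and 6 adjusted over the list alone), with Cxcr5, the follicle homing receptor gene, up by 0.80 (SE 0.14, adjusted p = 6.82e-04). B cell receptor and immediate early genes had 4 of 14 up and 4 down, also 4 and 4 adjusted over the list alone. Junb rose (1.28, SE 0.20, adjusted p = 1.89e-04) and Btg2, which restrains proliferation, fell (-0.88, SE 0.18, adjusted p = 0.00236). Neither list passed as a whole (camera adjusted p = 0.156 and 0.382).

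In the G1/S list 2 of 29 genes rose and 3 fell in the LZ, also 2 and 3 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0723). Cyclin genes in it went opposite ways: Ccnd2 went from 11.5 ± 2.81 to 149 ± 51.5 CPM (n = 4; log2 fold change 3.66, SE 0.39, adjusted p = 4.05e-06), with 1 anti-CD40 library at 226 CPM and the others at 114 to 130. Ccnd3 went from 486 ± 91.1 to 223 ± 19.9 CPM (-1.12, SE 0.18, adjusted p = 3.02e-04). Of 27 somatic hypermutation and DNA repair genes 1 rose and 2 fell, also 1 and 2 adjusted over the list alone (camera adjusted p = 0.156). Among those that fell was Hmces, which protects abasic sites (-1.87, SE 0.24, adjusted p = 3.70e-05). MHC class II presentation had 1 of 17 up and 3 down (1 and 4 adjusted over the list alone, camera adjusted p = 0.0514). Ifi30, a lysosomal thiol reductase gene, rose by 0.91 (SE 0.19, adjusted p = 0.00228). Plasma cell differentiation had 3 of 19 up and 4 down, also 3 and 4 adjusted over the list alone (camera adjusted p = 0.774); its median of 0.09 turned negative under upper quartile scaling. Interferon response genes had 3 of 17 up and 1 down, also 3 and 1 adjusted over the list alone (camera adjusted p = 0.987); their median was -0.13, while the mean (0.06) and the test pointed up.

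The largest rises in the LZ by the rule fixed before the data were examined were in Tnfrsf8, Tspan33, Slc29a2, Adgrg1, Il1r2, Fscn1, Carmil3 and Ccnd2, from 3.66 to 4.30 on the log2 scale. Tnfrsf8, which encodes CD30, went from 8.68 ± 2.48 to 178 ± 129 CPM (log2 fold change 4.30, SE 0.61, adjusted p = 7.19e-05). Tspan33, a tetraspanin gene of activated B cells, went from 10.7 ± 2.05 to 190.4 ± 61.4 CPM (4.11, SE 0.39, adjusted p = 1.61e-06). Slc29a2 rested on 62 against 3 UMI, a 17.1-fold rise with a counting interval of 5.57 to 85.0, and its 3 isotype UMI came from 1 library. The largest falls were in Cacna1i, Ngfr, Pxdc1, Ephx1, Klf2, Serpinb1a, Chst15 and Mxd4, from -4.82 to -2.53. Cacna1i, a calcium channel gene, rested on 2 against 60 UMI (36.3-fold lower, counting interval 9.63 to 307). Single libraries moved some of these values by over 1.5 times: Slc29a2 was at 7.24 and Adgrg1 at 4.56 (from 3.77) without isotype LZ library 1, and Carmil3 at 4.63 (from 3.69) without isotype LZ library 4. Without anti-CD40 LZ library 3, Cacna1i was at -7.34 and Pxdc1 at -3.78 (from -3.13). Mxd4, which like Mxd3 encodes a competitor of Myc, went from 32 ± 6.23 to 5.27 ± 1.66 CPM (-2.53, SE 0.35, adjusted p = 5.56e-05).

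In all, 1302 of 6824 genes passed in the LZ (edgeR, Benjamini-Hochberg adjusted p under 0.05), 740 higher and 562 lower, and 748 of them changed at least 2-fold. Myc and Cd40 were each higher in 4 of 4 anti-CD40 LZ libraries than in any isotype LZ library (exact permutation p = 0.0286, the smallest that 70 arrangements allow; adjusted p = 0.0327 over 8 tests). Of 22 lists tested with camera 12 passed, 6 up and 6 down, and 7 held with an estimated correlation: NF-kB targets (adjusted p = 0.00299), Myc targets (0.00891), LZ markers (0.0102), DZ markers (0.0102), G2/M (0.0146), FoxO1 and PI3K (0.0146) and B cell receptor signalling (0.0383). With the replicate number as a block the count was 2013. Without the libraries numbered 4 it was 1188, 685 higher and 503 lower, of which 989 were shared in direction with the 1302. Upper quartile scaling moved the median of all genes to -0.10 (log2) and the split to 596 higher and 758 lower, so the share of rises depended on the scaling. The authors' deposited table lists 1296 genes for this comparison at the same threshold, 1191 of them shared in direction.

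**Figure D1:**
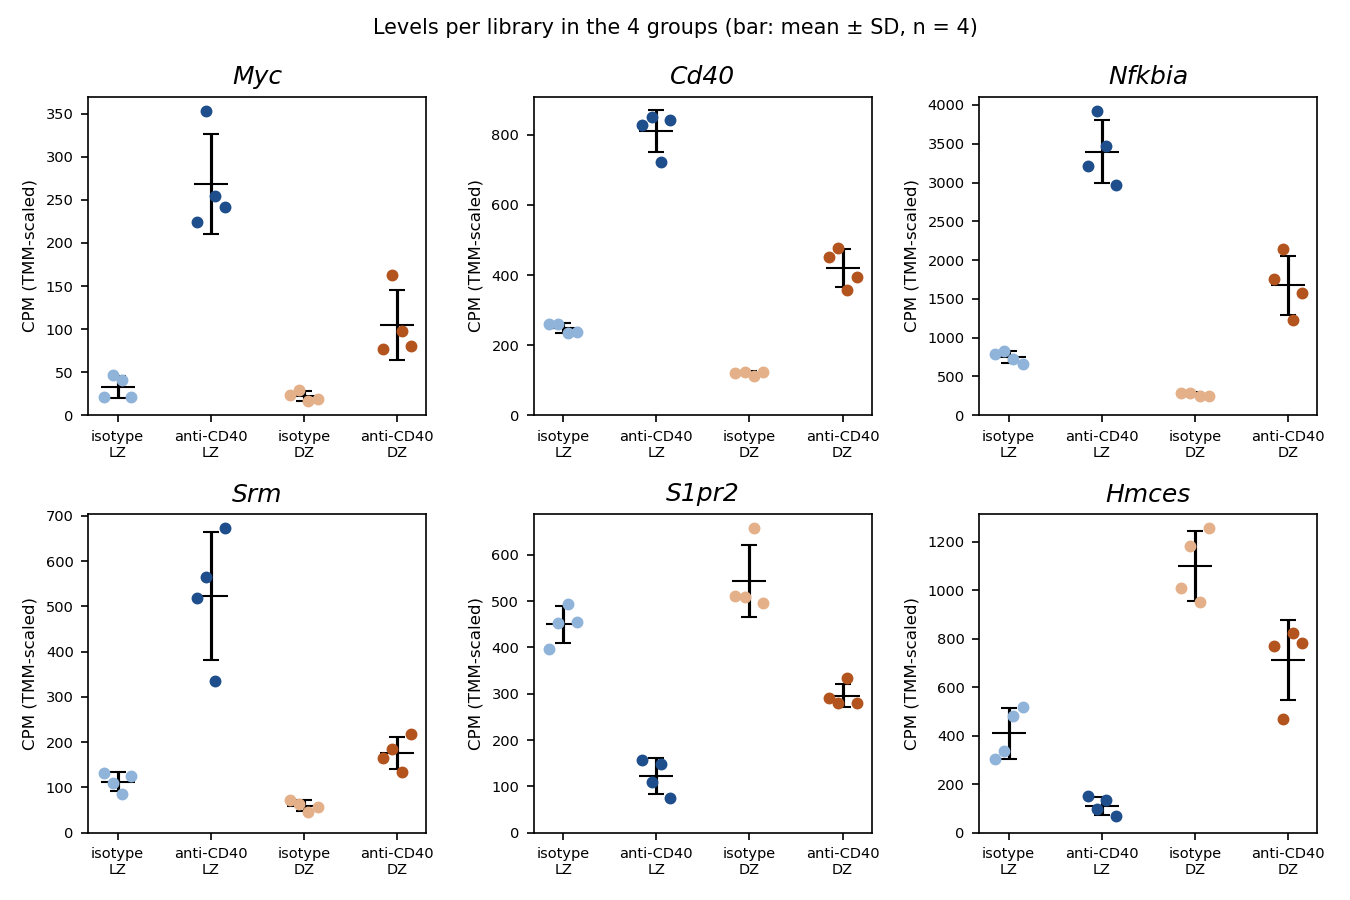
Levels of Myc, Cd40, Nfkbia, Srm, S1pr2 and Hmces in CPM (TMM-scaled) in each of the 16 libraries, by group; points are libraries and bars the mean ± SD (n = 4). Every anti-CD40 library lies above every isotype library of its zone for Myc and Cd40, and the mean of Myc is 269 ± 57.7 CPM in anti-CD40 LZ and 104 ± 40.4 CPM in anti-CD40 DZ.

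In the DZ anti-CD40 raised Myc from 21.9 ± 5.84 to 104 ± 40.4 CPM (mean ± SD, n = 4; log2 fold change 2.26, SE 0.30, adjusted p = 1.10e-04). Cd40 rose there from 121 ± 6.37 to 420.2 ± 54 CPM (1.80, SE 0.14, adjusted p = 1.32e-07). NF-kB targets rose: 17 of 36 passed and none fell (24 adjusted over the list alone), led by Nfkbia, from 270.3 ± 23.5 to 1675 ± 384 CPM (2.63, SE 0.17, adjusted p = 1.62e-08). Of 21 LZ markers 13 rose and none fell in these DZ cells (17 and 1 adjusted over the list alone), among them Irf4 (3.06, SE 0.26, adjusted p = 5.77e-07) and Fcer2a (1.70, SE 0.14, adjusted p = 5.77e-07). Myc targets rose in 14 of 51 cases, and in 36 adjusted over the list alone, with Gnl3 at 1.69 (SE 0.23, adjusted p = 1.60e-04) and Srm at 1.54 (SE 0.22, adjusted p = 3.22e-04).

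Some genes that regulate apoptosis or contact with T cells rose in the DZ. Of 22 apoptosis regulators 6 rose and none fell (9 and 3 adjusted over the list alone), including Bcl2l1, from 13.4 ± 7.26 to 123 ± 60.0 CPM (n = 4; log2 fold change 3.23, SE 0.40, adjusted p = 5.66e-05). Bid, which promotes apoptosis, was also among them (0.89, SE 0.16, adjusted p = 0.00239). Of 18 costimulation and adhesion genes 5 rose and 1 fell (8 and 1 adjusted over the list alone), with the adhesion ligand gene Icam1 at 1.30 (SE 0.19, adjusted p = 3.22e-04). Cell cycle lists were lower: the median of 34 G2/M genes was -0.31 with 33 of them negative, although none passed alone (also 0 adjusted over the list alone). The median of 29 G1/S genes was -0.33, with 1 member up and 1 down (1 and 2 adjusted over the list alone). Interferon response genes had 2 of 17 up and none down (3 adjusted over the list alone). Their camera call (adjusted p = 0.0108) was lost at adjusted p = 0.285 with an estimated correlation and at 0.303 without anti-CD40 DZ library 1 or 0.0517 without isotype DZ library 4. Of 30 B cell receptor signalling components none passed (also 0 adjusted over the list alone), and the list's camera adjusted p of 0.0491 became an adjusted p = 0.168 with an estimated correlation.

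The 8 largest rises in the DZ by the same rule (at least 20 CPM and no overlap between groups) were in Carmil3, Fam129c, Mgll, Bcl2l1, Irf4, Fscn1, Ebi3 and Nfkbia, from 2.63 to 3.70. Fam129c, a gene of B cells, went from 8.05 ± 2.96 to 101 ± 35.5 CPM (n = 4; log2 fold change 3.60, SE 0.32, adjusted p = 9.29e-07). Mgll, a lipase gene, went from 3.66 ± 0.862 to 44.9 ± 18.8 CPM (3.48, SE 0.36, adjusted p = 5.93e-06). Falls were few, with 10 genes lower and 3 of them at least 2-fold. Igsf8, Fgf11 and Add3 fell more than S1pr2 or Efnb1. Igsf8 had 31, 28, 22 and 22 UMI in isotype DZ libraries 1 to 4 and 10, 14, 8 and 6 in anti-CD40 DZ libraries 1 to 4. S1pr2 went from 544 ± 77.1 to 296 ± 25 CPM (-0.88, SE 0.18, adjusted p = 0.00937) and Efnb1 from 204 ± 21.6 to 113 ± 25.1 CPM (-0.87, SE 0.18, adjusted p = 0.00726). S1pr2 no longer passed without isotype DZ library 3 (adjusted p = 0.0563), which held 659 CPM against 497 to 511 in the others, or without anti-CD40 DZ library 2 (adjusted p = 0.0537). Efnb1 no longer passed without the latter (adjusted p = 0.0655).

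In the DZ 163 of 6824 genes passed (edgeR), 153 higher and 10 lower, and 746 had an unadjusted p under 0.05. Of 22 lists 9 passed with camera, 6 up and 3 down, and 7 held with an estimated correlation: NF-kB targets (adjusted p = 1.02e-04), LZ markers (9.57e-04), Myc targets (0.00644), apoptosis regulators (0.00504), G1/S (0.00504), costimulation (0.0118) and G2/M (0.0118). With the replicate number as a block, a pairing the labels do not state, the count was 427. Without anti-CD40 DZ library 2 it was 98, all higher, and without the libraries numbered 4 it was 222, 204 higher and 18 lower, with 146 of the 163 shared in direction. The authors' deposited table lists 190 genes here, 160 of them shared in direction.

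The responses of the zones resembled each other across genes. Of 740 genes that rose in the LZ and 153 that rose in the DZ, 134 rose in both, against 16.6 for independent lists (Fisher's exact test, one-sided p = 7.1e-112), and 7 fell in both against 0.824 (one-sided p = 2.4e-06). Fisher's test treats genes as independent draws, which they are not, and its p does not measure the spread between libraries. Of 163 genes called in the DZ 162 had the same sign in the LZ, and of 1302 called in the LZ 1214 had the same sign in the DZ. Across 6824 genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.676 and Spearman rho = 0.582. The zones shared no library. However, LZ and DZ libraries of the same number and treatment correlated at -0.124 to 0.657 once group means were removed. Spread shared in this way could raise the correlation and the overlap.

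**Figure D2:**
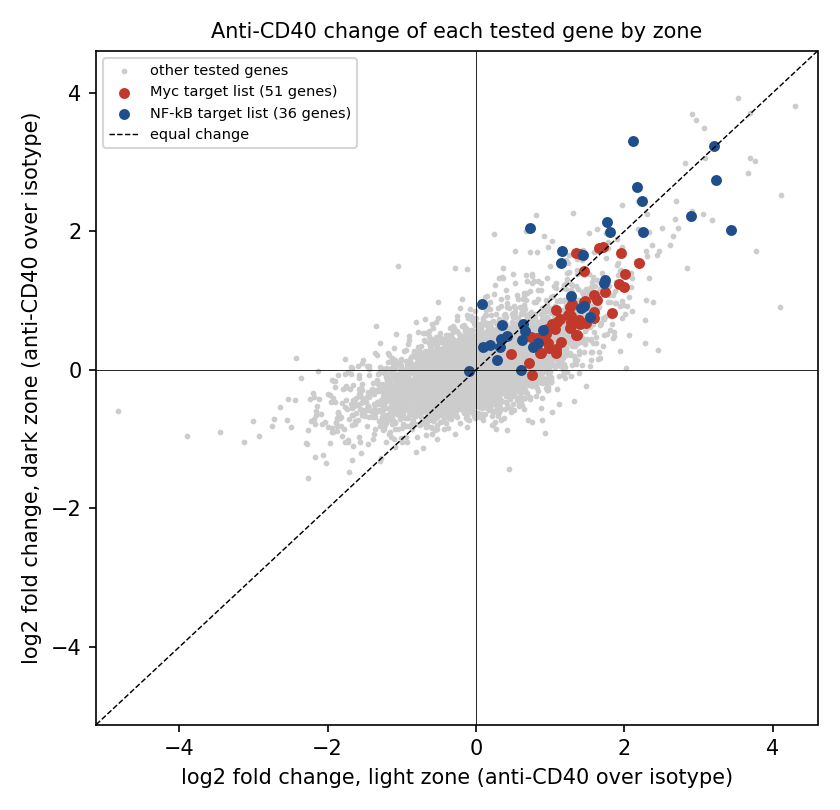
Log2 fold change of anti-CD40 over isotype in the LZ (x axis) and the DZ (y axis) for each of 6824 tested genes, with 51 Myc target genes in red and 36 NF-kB target genes in blue; the dashed line marks equal change. The median of the Myc target list is 1.29 in the LZ and 0.69 in the DZ, and that of the NF-kB list 1.15 and 0.94.

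Whether the anti-CD40 change differed between zones was tested as an interaction (LZ change minus DZ change). Zones were assigned by a sort after the antibody. Responding cells that changed gate could therefore enter this difference and the comparison of zones under anti-CD40. In the main edgeR fit, with TMM factors and no replicate block, Cacna1i was the only gene that passed (difference -4.22, SE 0.68, adjusted p = 0.0388). It had 24.1 ± 4.82 and 0.564 ± 1.13 CPM in isotype and anti-CD40 LZ and 43.5 ± 5.66 and 29.1 ± 9.73 CPM in the DZ (n = 4). For Myc the difference was 0.80 (log2, SE 0.42, adjusted p = 0.620) and for Cd40 -0.09 (SE 0.19, adjusted p = 0.921), neither past the threshold. By list, 47 of 51 Myc targets had the larger change in the LZ, with a median difference of 0.59. The NF-kB list had a median of -0.01, a mean of 0.04 and 17 of 36 on the LZ side (camera adjusted p = 0.869). The camera call of the Myc target list (adjusted p = 1.42e-13) was lost at adjusted p = 0.0761 with an estimated correlation; 3 members passed adjusted over the list alone, against none over all genes. DZ markers, with 16 of 18 members and a median of -0.67, and FoxO1 and PI3K genes, with 10 of 16 members and a median of -0.68, went lower in the LZ than in the DZ and held with an estimated correlation (adjusted p = 0.0194 and 0.0448). Adjusted over the list alone, 0 DZ markers and 6 FoxO1 and PI3K genes passed; over all genes Foxo1 had -0.73 (SE 0.24, adjusted p = 0.371). LZ markers did not differ in sum (median -0.03, mean 0.08, camera adjusted p = 0.974, 0 adjusted over the list alone).

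For the interaction 1 of 6824 genes passed with edgeR and 38 with DESeq2, 107 with the replicate number as a block (111 within treatment, 163 with a GC correction as well), and 586 had an unadjusted p under 0.05. In 20 simulated sets the interaction test recovered on average 11.5% of 2-fold changes in the LZ and 12% in the DZ. In such sets most differences of that size were missed. Each set changed a preset number of genes in 1 zone and held no spread shared by replicate number, so recovery in the data may differ. Without anti-CD40 LZ library 3 the Cacna1i difference was -6.74, since the 2 UMI of its group came from that library. The Cacna1i call was lost without the libraries numbered 4 (adjusted p = 0.0922) and without any 1 of 13 libraries (each except anti-CD40 LZ library 3, isotype DZ library 4 and anti-CD40 DZ library 1), at adjusted p from 0.0529 to 0.199.

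**Figure D3:**
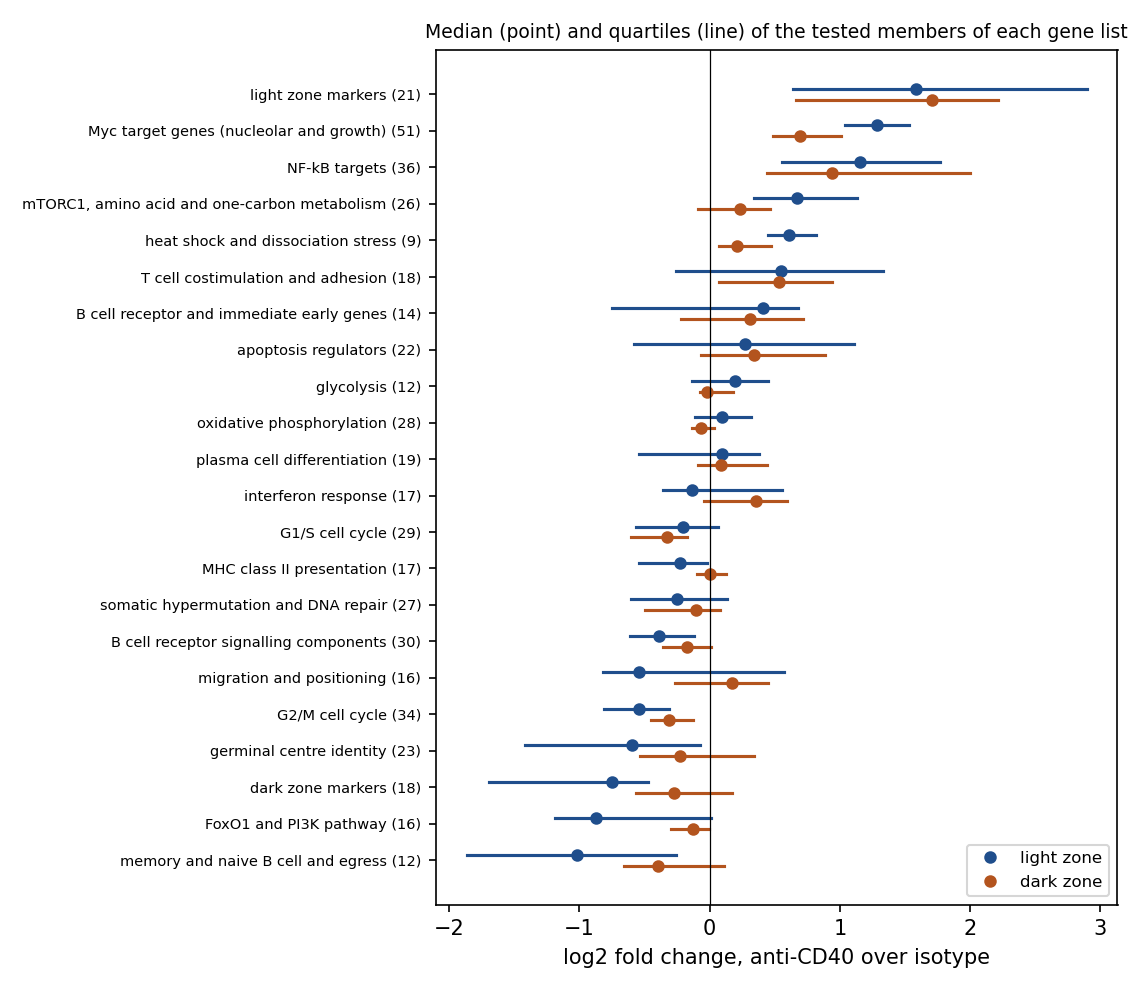
Median (point) and quartiles (line) of the log2 fold change of anti-CD40 over isotype among the tested members of 22 gene lists, in the LZ (blue) and the DZ (orange), with the number of members in parentheses. LZ markers, Myc targets and NF-kB targets lie highest in both zones; the small medians of oxidative phosphorylation and plasma cell genes in the LZ and of MHC class II genes in the DZ change sign between scalings.

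Under isotype, the LZ and DZ groups differed in LZ markers. The cells had been sorted by zone, so a difference in zone markers, here and under anti-CD40, is in part a check of the sort. Cd40 was at 248 ± 14.1 CPM in the LZ and 121 ± 6.37 in the DZ (n = 4; log2 fold change 1.04, SE 0.14, adjusted p = 2.01e-04). Myc was at 32.5 ± 13 and 21.9 ± 5.84 CPM and did not pass (0.54, SE 0.33, adjusted p = 0.572). Of 21 LZ markers 13 were higher in the LZ and none lower (19 adjusted over the list alone), such as Fcer2a (1.53, SE 0.14, adjusted p = 5.51e-06) and the chemokine receptor gene Ccr6 (3.12, SE 0.37, adjusted p = 6.28e-05). Both genes also belong to the memory, naive and egress list. Of its 12 tested genes 3 were higher in the LZ under isotype and 0 lower, with a median of 0.45. By these genes, naive or memory B cells among the sorted LZ cells cannot be told apart from LZ identity. NF-kB targets were higher in 9 of 36 cases and lower in 1 (17 and 1 adjusted over the list alone), with Nfkbia at 1.47 (SE 0.16, adjusted p = 2.96e-05). G2/M genes were lower in 5 of 34 cases and higher in none (6 adjusted over the list alone). The cyclin gene Ccnb2 was at 122 ± 9.76 CPM in the LZ and 270.2 ± 23.8 in the DZ (-1.15, SE 0.19, adjusted p = 0.00221).

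Myc targets leaned to the LZ in all 51 cases under isotype, with a median of 0.41, but 3 passed (7 adjusted over the list alone) and the camera call (adjusted p = 1.02e-10) was lost at adjusted p = 0.0849 with an estimated correlation. MHC class II genes had a median of 0.38 with 1 of 17 higher (4 adjusted over the list alone), a call (camera adjusted p = 9.08e-06) also lost at adjusted p = 0.0693 with an estimated correlation. DZ markers had 2 of 18 lower in the LZ and none higher (3 and 2 adjusted over the list alone). Their call (camera adjusted p = 0.0484) was lost at adjusted p = 0.0860 with an estimated correlation and without isotype LZ library 1, 2 or 3 or isotype DZ library 3 or 4 (adjusted p = 0.0677 to 0.118) or after a GC correction (0.108). Outside the lists, Rgcc (-2.20, SE 0.21, adjusted p = 5.51e-06), a cell cycle regulator gene, and Pafah1b3 (-1.96, SE 0.19, adjusted p = 5.69e-06), a phospholipase subunit gene, were among the 8 lowest in the LZ by the naming rule. Hmces was at 411 ± 105 CPM in the LZ and 1099.6 ± 144 in the DZ (-1.42, SE 0.23, adjusted p = 0.00195).

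Under isotype 152 genes passed (edgeR), 88 higher and 64 lower in the LZ, and the authors' deposited table lists 204, of which 146 were shared in direction. With camera 11 of 22 lists passed and 3 held with an estimated correlation: LZ markers (adjusted p = 0.00286), NF-kB targets (0.0121) and G2/M (0.0278). The gene count was 235 with DESeq2, 101 when only the groups compared were fitted, 212 without the libraries numbered 4 (131 shared in direction). It was 88, 85, 98, 78 and 72 without isotype LZ library 1, LZ library 2, DZ library 1, DZ library 2 and DZ library 3. With the replicate number as a block the count was 433 (460 within treatment).

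After anti-CD40 Myc differed between zones, at 269 ± 57.7 CPM in the LZ and 104 ± 40.4 in the DZ (n = 4; log2 fold change 1.34, SE 0.26, adjusted p = 0.00245), while Cd40 differed by 0.95 (SE 0.13, adjusted p = 1.25e-04). Myc targets were higher in the LZ in 42 of 51 cases and lower in none (49 adjusted over the list alone). Among them Srm was at 1.57 (SE 0.21, adjusted p = 1.20e-04) and the translation factor gene Eif5a at 0.88 (SE 0.13, adjusted p = 1.89e-04). LZ markers were higher in 16 of 21 cases (19 adjusted over the list alone) and NF-kB targets in 12 of 36 (19 adjusted over the list alone), with none lower in either. DZ markers were lower in 7 of 18 cases and higher in 1 (9 and 1 adjusted over the list alone). Foxo1 was among the lower (-1.24, SE 0.18, adjusted p = 1.76e-04) and Samsn1 was the higher (1.93, SE 0.36, adjusted p = 0.00156). G2/M genes were lower in 10 of 34 cases (16 adjusted over the list alone), with the centromere gene Cenpa at -1.23 (SE 0.17, adjusted p = 1.20e-04).

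After anti-CD40, Hmces was at 112 ± 37.1 CPM in the LZ and 712 ± 164 in the DZ (n = 4; log2 fold change -2.66, SE 0.25, adjusted p = 2.18e-06), where 1 library held 469 CPM and the others 772 to 825. Pafah1b3 differed by -2.37 (SE 0.20, adjusted p = 1.24e-06), with 224 CPM in 1 LZ library and 144 to 155 in the others. Neil1, a DNA glycosylase gene of the germinal centre identity list, differed by -1.84 (SE 0.22, adjusted p = 3.29e-05). That list had 7 of 23 lower and 1 higher (10 and 1 adjusted over the list alone), with a camera call (adjusted p = 4.60e-05) lost at adjusted p = 0.0504 with an estimated correlation. In the mTORC1, amino acid and one-carbon list 7 of 26 were higher and none lower (11 adjusted over the list alone), a camera call (adjusted p = 5.39e-07) lost at adjusted p = 0.0668 with an estimated correlation.

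After anti-CD40 786 genes passed between zones (edgeR), 419 higher and 367 lower in the LZ, and 740 of 808 in the authors' deposited table were shared in direction. With camera 12 of 22 lists passed and 6 held with an estimated correlation: LZ markers (adjusted p = 0.00374), DZ markers (0.00374), Myc targets (0.00621), G2/M (0.00746), NF-kB targets (0.00766) and FoxO1 and PI3K (0.0105). The count was 1533 with the replicate number as a block (1481 within treatment), 903 without the libraries numbered 4 (443 higher and 460 lower, 671 shared in direction), 480 without anti-CD40 LZ library 2 and 498 without anti-CD40 DZ library 3. Upper quartile scaling gave 341 higher and 472 lower.

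Markers of other cell types were few in the file. Of 28 T cell markers 5 were listed, at a summed 276 ± 46.9 CPM of the library total in isotype LZ, 138 ± 19.9 in anti-CD40 LZ, 320.3 ± 32.5 in isotype DZ and 228 ± 50.8 in anti-CD40 DZ (SD, n = 4). Cd3 and Cd4 chain genes were not among them. The 5 were Cd2, Lck, Lat, Tcf7 and Tox, and Cd2 and Lck held most of the isotype LZ sum. In the LZ Cd2 went from 111 to 24.8 CPM and Lck from 117 to 78.6, so the fall lay mostly in Cd2. Of 30 myeloid and dendritic cell markers 8 were listed, at 2097 ± 85.7, 687 ± 194, 2364 ± 222 and 1759 ± 259 CPM in the same order, most of it from the lipoprotein gene Apoe and the protease inhibitor gene Cst3. Apoe, named after its values were seen, went from 1599.5 ± 65.4 to 428 ± 172 CPM in the LZ (log2 fold change -1.90, SE 0.22, adjusted p = 1.13e-05) and from 1647 ± 187 to 1194 ± 232 in the DZ (-0.46, SE 0.21, adjusted p = 0.416). The macrophage genes Lyz2 and Tyrobp lay between 2.17 and 7.80 CPM in every group. Of 23 stromal and follicular dendritic cell markers 4 were listed, at 108 ± 59.1, 34.8 ± 3.92, 48.7 ± 16.3 and 45.2 ± 10.7 CPM. In isotype LZ most of it came from Pecam1 (71.0 ± 19.6 CPM) and Mfge8 (32.7 ± 47.0 CPM). The SD of Mfge8 exceeded its mean there, so that level was uneven between libraries. Of 14 red cell and platelet markers 1 was listed, at 3.90 ± 2.97, 0.978 ± 1.33, 5.79 ± 1.5 and 3.77 ± 2.04 CPM. None of the 15 mitochondrially encoded genes was listed, and none of these 5 lists had enough tested genes for a list test.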

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

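The tests chosen only after the result was seen were the correlation with GC content, the comparison of list ratios and the grouping of splits by libraries exchanged; the other tests in this part were planned or written before their results were seen.

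Of 143 sets of 4 libraries examined, 11 held a library far from the other 3, and chance gives about 1 in 20 sets. For Ccnd2, anti-CD40 LZ library 2 had 226 CPM against 114 to 130, and for Pafah1b3 anti-CD40 LZ library 1 had 224 against 144 to 155. For S1pr2, isotype DZ library 3 had 659 CPM against 497 to 511; for Cep250, isotype DZ library 4 had 85.5 against 58.1 to 60.8. In anti-CD40 DZ library 2, Hmces had 469 CPM against 772 to 825 and Ptprs 4.56 against 1.56 to 2.05. Slc29a2 had 4.03 CPM in isotype LZ library 1 and Cacna1i 2.25 in anti-CD40 LZ library 3, and the other libraries of those groups had 0. Anti-CD40 LZ library 3 held 914975 UMI against 675629 to 709688 and 9181 genes against 8982 to 9014, and in anti-CD40 LZ library 1 the 20 most abundant genes took 17.1% of UMI against 14.4 to 14.7%.

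The anti-CD40 change differed between zones, by the interaction test, for Cacna1i (-4.22 on the log2 scale, SE 0.68, adjusted p = 0.0388), a gene with 2 UMI in anti-CD40 LZ. By camera it also differed for 13 lists. The median difference was positive for Myc targets (0.59), mTORC1 and one-carbon metabolism (0.53), heat shock (0.36), oxidative phosphorylation (0.21) and glycolysis (0.18). It was negative for FoxO1 and PI3K (-0.68), DZ markers (-0.67), memory and naive cells (-0.48), germinal centre identity (-0.47), interferon response (-0.35), MHC class II (-0.29), G2/M (-0.26) and B cell receptor signalling (-0.24). With an estimated correlation 2 of the 13 passed, DZ markers (adjusted p = 0.0194) and FoxO1 and PI3K (0.0448), and the adjusted p of the other 11 ran from 0.0542 to 0.437.

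The libraries numbered 4 differed from the other 12 in 2451 genes with group in the model, 1086 higher and 1365 lower. That difference followed GC content (Spearman rho = 0.523 over 6738 genes, which are not independent replicates), with a median of -0.62 in genes whose GC content was at most 39.2% and 0.29 in those at or above 51.4%, so a candidate explanation is a bias in library preparation. The GC trend was not the whole difference, since 1877 genes still differed after the correction, 1340 of them shared in direction with the 2451. Fewer UMI did not account for it either, since 2097 genes differed after all libraries were thinned to 493131 UMI. What underlies this difference stays open, and no biological explanation was tested, since the labels give none.

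The Myc target list rose more in the LZ than in the DZ. For the NF-kB list no such difference was seen, with a median of -0.01 (jackknife SE 0.253), a spread that leaves room for a moderate one. A response weaker in the DZ by 1 common factor would give equal ratios, but the mean DZ change over the mean LZ change was 0.609 (jackknife SE 0.119) for Myc targets and 0.971 (SE 0.115) for NF-kB targets, and the ratios differed by 0.362 (SE 0.102), which argues against 1 common factor for these lists. The lists were picked after their difference was seen and the ratios partly restate it, so the gap may be overstated. GC bias did not account for it, since the median difference of the Myc target list was 0.576 (SE 0.21) after the correction and 0.589 (SE 0.17) before. The zone itself, which the design names, stays open and untested as the cause, and the list's interaction call rests on the preset correlation (adjusted p = 0.0761 with an estimated correlation).

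Other splits of the same libraries were used to ask whether chance can be excluded. For genes the real split alone gave as many: 1302 in the LZ (1 of 35, highest other 0), 163 in the DZ (1 of 35, 0), 152 under isotype (1 of 35, 2) and 786 under anti-CD40 (1 of 35, 0). These shares do not by themselves exclude chance, since mixed groups carry the real difference in their spread, which lowers the counts of the other splits. For the interaction 1 of 100 splits, the real one, gave as many as 1 gene (highest other 0), a margin of 1 gene that says little, since the Cacna1i call is lost without any 1 of 13 libraries.

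For lists 3 of 35 splits in the LZ gave as many as the real 12 (highest other 13) and 8 of 35 in the DZ as many as the real 9 (highest other 11), so this count does not exclude chance. It does not speak for chance either: the others with as many had 1 library per group exchanged and so keep part of the real contrast. The 18 splits with 2 libraries per group exchanged gave at most 3 lists in the LZ and 4 in the DZ, and are too few for a share under 0.05. Fewer splits gave as many lists under isotype (1 of 35, 11 lists, highest other 10), under anti-CD40 (1 of 35, 12 lists, highest other 11) and for the interaction (2 of 100, 13 lists, highest other 14), but these splits have the same limits and the margins are small, so chance is left open here too.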

How the results depend on the processing

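Chosen after the data were seen were the alternatives without the libraries numbered 4 and with the GC correction, alone or with the replicate block; the rest were planned.

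No call of a named gene or list reversed its direction under any alternative in which it was run. List tests were not run with DESeq2, limma-voom, upper quartile factors, the stricter filter or a fit of only the groups compared. Under upper quartile factors the split of genes in the LZ went from 740 higher and 562 lower to 596 and 758, and between zones under anti-CD40 from 419 and 367 to 341 and 472. The LZ medians of oxidative phosphorylation (0.10) and plasma cell genes (0.09), neither called, became -0.01 and -0.02. Of 243 calls of named genes 179 held under every alternative run for them, 61 were lost when 1 library was left out and 41 under another alternative. Under the stricter filter 227 of the 243 could be checked. Of 57 list calls 25 held in every alternative run for lists, 15 were lost without 1 library and 32 under another alternative. The calls of Myc and Cd40 held under all alternatives run: leaving out 1 library, Myc ranged from 2.85 to 3.28 (log2) in the LZ, from 1.95 to 2.42 in the DZ and from 1.15 to 1.61 between zones under anti-CD40, and Cd40 from 1.64 to 1.77 in the LZ and from 1.75 to 1.88 in the DZ.

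Leaving out 1 library gave 876 to 1240 genes in the LZ, 98 (without anti-CD40 DZ library 2) to 181 in the DZ, 480 (without anti-CD40 LZ library 2; 498 without anti-CD40 DZ library 3) to 726 between zones under anti-CD40, and 0 to 2 for the interaction. Under isotype it gave 72 (without isotype DZ library 3) to 151, with 88 and 85 without isotype LZ library 1 or 2 and 98 and 78 without isotype DZ library 1 or 2; fewer samples enter each of these fits. Lists ranged from 11 to 14 in the LZ, 7 to 11 in the DZ, 9 to 12 under isotype, 10 to 12 under anti-CD40 and 8 (without anti-CD40 DZ library 1) to 14 for the interaction.

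The replicate number as a block gave 2013 genes in the LZ, 427 in the DZ, 107 for the interaction, 433 under isotype and 1533 under anti-CD40, and within treatment 111, 460 and 1481 for the last 3. With the GC correction the block gave 2100, 483, 163, 505 and 1615 in the same order. The labels do not state that numbers pair libraries, and the block was fixed as an alternative before the data were examined. Libraries of the same number correlated at -0.205 to 0.657 once group means were removed. Of 16 libraries 11 matched best with their own number, and no chance level was computed for that. The range was 0.134 to 0.522 for number 1, 0.0157 to 0.316 for number 2, -0.205 to 0.0655 for number 3 and 0.492 to 0.657 for number 4. The libraries numbered 4 thus stood out, and a pairing of the other numbers was less clear. If spread is shared by number, the unblocked counts may be low. The GC correction alone gave 1431, 192, 2, 192 and 914 genes. Without the libraries numbered 4 the interaction had 0 genes with edgeR. DESeq2 gave 235 genes under isotype and 38 for the interaction, where it set no adjusted p for 3572 genes, and fitting only the groups compared gave 101 under isotype; upper quartile factors gave 2 for the interaction. For these counts the cause was not tested.

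With an estimated correlation 7 lists passed in the LZ, 6 under anti-CD40, 3 under isotype and 2 for the interaction; fry gave 19 in the LZ and 4 for the interaction. The correlation of the changes in both zones was 0.676 over all tested genes, 0.830 over genes called in at least 1 zone, a choice that favours large changes, and 0.594 to 0.689 without 1 library. Leaving immunoglobulin genes out could not give a value, since none is listed. Depth limits the low end: 3 UMI in the shallowest library correspond to 6.08 CPM.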

Other observations

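The test in this part was chosen after the counts of genes were seen.

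More genes passed for anti-CD40 in the LZ (1302) than in the DZ (163), and a candidate explanation is a smaller response in the DZ. To test this, the 200 genes with the smallest p for the average change of both zones were picked in 2 of 4 libraries of each group and measured in the others, in 6 ways. The median ratio of the DZ change to the LZ change was 0.637 (range 0.537 to 0.708), and 147 to 168 of the 200 genes changed more in the LZ, so the values go with a smaller DZ response. Among genes that passed in the LZ the median size of the change was 1.08 (log2) there and 0.41 in the DZ, a comparison that favours the LZ; among genes that passed in the DZ it was 1.46 in the LZ and 1.33 in the DZ. The test does not say whether fewer DZ cells responded or each responded less. Cells were taken 4 h after the antibody and sorted by gates that the labels do not give. Responding DZ cells sorted as LZ could also lower the DZ change, and that was not tested.

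Ribosomal protein genes took 23.5% of UMI in isotype LZ, 24.2% in anti-CD40 LZ, 22.6% in isotype DZ and 22.2% in anti-CD40 DZ (group means, n = 4).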
